A study of Homo sapiens with 6 samples.

How the data were processed

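Total RNA of THP-1 cells was extracted with a Qiagen RNeasy kit and made into libraries with a SMARTER mRNA-seq kit, per the labels' protocols. Groups came from the treatment label, Lenti-Con or Lenti-Vsir, with 3 libraries each. The replicate numbers came from the library names. The description of the series' design speaks of single-cell libraries of grafts, which is not the assay of these samples and was not used here.

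The values came from 1 table of 34392 genes for the 6 libraries. Its raw counts per gene were deposited by the authors without normalization, per the file headers and the whole-number values, with library totals of 62541113 to 72956319. Its FPKM values were made by the authors, per the file headers, as counts per kilobase of gene and scaled to the fragments of the library. The submitters' processing notes listed the builds GRCm38, mm10 and hg38 without a role. The gene identifiers and coordinates of the table were human and on GRCh38, checked at VSIR against a RefSeq annotation of that build. Correlations of log2 CPM ran from 0.988 to 0.995 within the groups and from 0.989 to 0.995 between them. The aligner, the counter, the annotation release and the strand setting are not given in the sources used here, so values of overlapping, antisense and near-identical genes are uncertain.

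Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 20480, and libraries were scaled by TMM. The test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment at 0.05. The design written before the data were examined named limma on log2(FPKM + 1) and, where counts were given, edgeR in its place; counts were given, and limma on FPKM served as an alternative. Levels are CPM from TMM-scaled totals, as mean ± SD. Intervals are 95% intervals from the fitted log2 difference and its SE. A single value was also tested by an exact permutation test.

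Before the data were examined, 42 gene lists were fixed, and 913 of their 981 symbols matched the table, some of the rest being older aliases of listed symbols. The 41 lists with at least 5 tested members were tested by camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The camera test compares a list with all other genes, while fry asks whether its genes move on balance in 1 direction. GO and KEGG terms of the deposited table with 15 to 500 tested genes were tested by camera.

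The named genes were VSIR, the genes past the threshold with the largest differences, and members of each list. As no gene passed, the 5 smallest p-values in each direction were taken instead, keeping the other conditions of that rule: a symbol, a mean of at least 2 FPKM in a group and groups that did not overlap. From each list the 2 members with the highest mean FPKM were taken. The values of 1 gene taken by this rule are not reported. Genes outside this rule are named as chosen after their values were seen.

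The fits were tested on simulated data for this comparison, drawn from the gene means, dispersions and totals of these libraries with 200 changed genes among 19866. The test recovered 8 of 50 genes changed 1.25-fold, 17 of 50 at 1.5-fold, 22 of 50 at 2-fold and 40 of 50 at 4-fold. Of those with at least 10 CPM it recovered 8 of 25, 17 of 19, 17 of 17 and 24 of 24, and it called 11 unchanged genes. With no gene changed it called 4 of 19850 genes, with 928 at an unadjusted p under 0.05. A simulated list of 40 genes shifted by a log2 value of 0.2 was called with the preset correlation and was not called with an estimated one.

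Replicates differed by more than counting noise in every pair of a group, over genes with at least 50 counts, with a chi-square per degree of freedom from 13.2 to 26.0, and each library was counted as 1 replicate. Alternatives were 18 other fits, of which 15 were fixed before the data were examined, the omission of each of the 6 libraries in turn, and the 2 other list tests. The other fits covered DESeq2 1.42.0, no low-count filter, RLE scaling, the replicate number as a block, protein-coding genes, a 2-fold minimum and limma on FPKM with other pseudocounts (0.1 and 5), filters (none and 5), scalings and variance models. Those chosen after seeing the data were limma-voom, a minimum count of 50, and removal of trends on GC content and gene length, for which 94.3% of tested genes had a GC value.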

Results

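RNA from THP-1 cells, a human monocytic leukaemia line, was sequenced after treatment with a control lentivirus (Lenti-Con) or with a lentivirus named for VSIR (Lenti-Vsir). VSIR encodes VISTA, an inhibitory receptor of the B7 family carried by myeloid cells. Each group held 3 libraries. The labels did not say that these came from separate cultures, so p-values measured only the spread between these samples, which may be technical. The Lenti-Con libraries held 70459574, 65705228 and 64005766 counts and the Lenti-Vsir libraries 62541113, 68623308 and 72956319 counts, in the order of their replicate numbers. Mitochondrial transcripts took 5.54% to 5.92% of the counts and ribosomal protein genes 2.45% to 2.73%. The most abundant transcripts were MT-CO1 with 1.34% of counts, the secreted glycoprotein gene CHI3L1 with 1.27% and CAP1 with 1.05%.

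The comparison asked whether VSIR, and genes of inflammation and antigen presentation, differed between the vectors. VSIR transcripts differed little between them, and no single gene passed the test. Of 41 gene lists fixed beforehand, camera with a preset correlation called 11, with small differences: type I interferon, MHC class II and NF-kB genes lay lower in Lenti-Vsir, and S phase and mitosis genes higher. None of these list calls held with an estimated correlation between genes. That test also lost a simulated shifted list of independently drawn genes, so the loss need not come from correlation. Other splits of the 6 libraries also called several of the lists. Of 10 splits, the real one included, 7 called the interferon list, 9 mitosis, 8 ribosomal proteins and 5 oxidative phosphorylation. The granule genes list was called by 4, S phase by 3 and MHC class II by 2. Only the real split called the other 4 lists, but the 11 lists were picked by its calls. Some lists were called only by splits that were not the real one. The amino acid response and ATF4 target list was called by 6 of these, and the LXR, MHC class I and interferon gamma lists by 2 each. Cholesterol synthesis, mitochondrially encoded, MYC target and lysosome lists were each called by 1.

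VSIR, ENSG00000107738 on the minus strand of chromosome 10 from 71747556 to 71773520 (GRCh38), measured 47.2 ± 4.05 and 55.1 ± 6.07 CPM with Lenti-Con and Lenti-Vsir (SD, n = 3 each; CPM are counts scaled to library totals). The single libraries held 49.7, 49.3 and 42.5 CPM against 61.2, 55.2 and 49.0 CPM, so the ranges overlapped. The fitted ratio was 1.17 with a 95% interval from 1.02 to 1.35, a log2 difference of 0.22 (SE 0.091). Its adjusted p was 0.9998 by the quasi-likelihood test of edgeR, and 0.033 before adjustment. A two-sided exact permutation test of the 6 values gave p = 0.3, where 0.1 is the smallest value this design allows. The labels did not say whether the vector was meant to raise or to silence VSIR, and sequence of the vector itself was not analysed here.

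**Figure D1:**
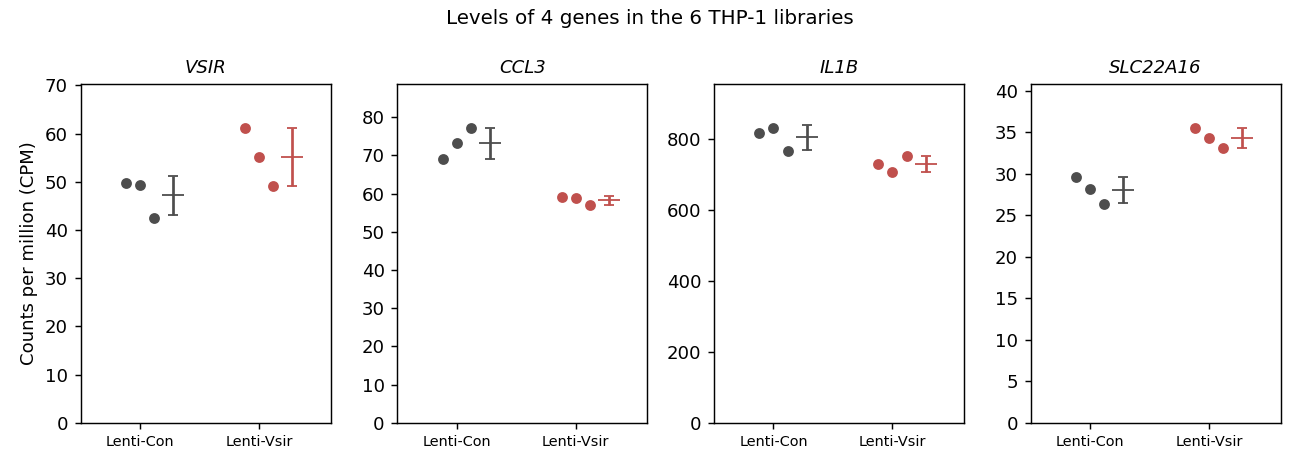
CPM (y axis, from 0) of VSIR, CCL3, IL1B and SLC22A16 in each library (points) of the Lenti-Con and Lenti-Vsir groups (x axis), with the mean and SD of 3 libraries as bars. VSIR ranges overlapped between the groups, while CCL3 averaged 73.2 CPM with Lenti-Con and 58.3 CPM with Lenti-Vsir without overlap.

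Of 20480 genes tested, edgeR called 0 higher and 0 lower in Lenti-Vsir at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 844 genes, 408 higher and 436 lower, where 1024 would be expected by chance. DESeq2 called 8 genes higher and 18 lower, limma-voom 1 higher and 0 lower, and limma on FPKM 0 in either direction. Among 9450 genes with a mean of at least 10 CPM, 98.2% differed by less than 1.2-fold and 98.3% had a 95% interval inside 1.5-fold. In the same set, 320 genes were higher and 548 lower in all 3 Lenti-Vsir libraries than in any Lenti-Con library, 9.19% of the set, where chance gives 10%. Without Lenti-Vsir 2 edgeR called 3 genes higher and 2 lower, without Lenti-Vsir 3 it called 4 lower, and without Lenti-Con 3 it called 1 lower.

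The smallest p-values among genes with lower values in Lenti-Vsir, under the rule for named genes, belonged to CCL3, LIMS1, FAM3C, TCEA1P2 and PI4K2B. CCL3, a chemokine that draws monocytes and T cells, measured 73.2 ± 4.02 and 58.3 ± 1.17 CPM with Lenti-Con and Lenti-Vsir, a log2 difference of -0.33 (SE 0.056) with an edgeR adjusted p of 0.66 over all genes. LIMS1, which encodes the adhesion adaptor PINCH1, measured 732 ± 39.7 and 621 ± 7.01 CPM, and the secreted factor gene FAM3C 54.2 ± 1.12 and 43.9 ± 2.498 CPM. PI4K2B, a phosphatidylinositol kinase gene, measured 34.7 ± 1.92 and 27.2 ± 1.88 CPM, and TCEA1P2 4.55 ± 1.84 and 1.51 ± 0.467 CPM. DESeq2 called each of these 5 genes, with adjusted p of 0.00085 for CCL3 and TCEA1P2, 0.0072 for LIMS1, 0.012 for FAM3C and 0.031 for PI4K2B. These were the smallest adjusted p over the alternatives, and the largest was 0.9999 for each. CCL3 and LIMS1 have near-identical copies in the genome and TCEA1P2 is named as a pseudogene, so their counts are uncertain.

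Of the genes with higher values in Lenti-Vsir, SLC22A16, a carnitine transporter gene, had the smallest p under that rule. SLC22A16 measured 28.1 ± 1.601 and 34.3 ± 1.21 CPM with Lenti-Con and Lenti-Vsir, a ratio of 1.22 (95% interval 1.10 to 1.36). The protease gene ADAMTS15 measured 36.7 ± 2.58 and 44.5 ± 0.758 CPM, the hydroxylase gene P4HTM 17.0 ± 0.0990 and 20.7 ± 0.794 CPM, the intermediate filament gene NES 18.3 ± 1.52 and 22.9 ± 0.985 CPM, and the DNA glycosylase gene NEIL1 14.1 ± 0.298 and 17.8 ± 1.53 CPM. The edgeR adjusted p was 0.9998 for each of these 5 genes, and no alternative called any of them.

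Genes of the MHC class II presentation list lay lower in Lenti-Vsir, by a small difference. The median log2 difference was -0.09, with 16 of 18 members below 0. The list passed camera with a preset correlation (adjusted p = 0.019) and was lost with an estimated correlation (adjusted p = 0.43). No member passed edgeR over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05, and DESeq2 called 0 of them. The thiol reductase gene IFI30 measured 459 ± 32.6 and 431 ± 31.1 CPM with Lenti-Con and Lenti-Vsir, and the protease gene CTSL 1299 ± 42.8 and 1275 ± 70.9 CPM. Of members chosen after their values were seen, the invariant chain gene CD74 measured 180.0 ± 5.73 and 167 ± 7.46 CPM, and HLA-DRB5, which shares reads with other DRB genes, 27.5 ± 0.160 and 23.8 ± 0.753 CPM. Without Lenti-Con 2, Lenti-Con 3, Lenti-Vsir 2 or Lenti-Vsir 3 the adjusted p was 0.054, 0.12, 0.18 and 0.096, in a range from 0.0033 to 0.18 over all other fits. The MHC class I presentation list, with a median of -0.05 and 17 of 21 members below 0, did not pass (camera adjusted p = 0.10), and B2M measured 1472 ± 67.1 and 1429 ± 60.3 CPM and CALR 1158 ± 31.3 and 1119 ± 59.9 CPM.

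The inflammatory cytokines list did not pass, with a median of -0.10 and 14 of 18 members below 0 (camera adjusted p = 0.10, and 0.48 with an estimated correlation). IL1B, the gene of interleukin 1 beta, measured 805 ± 34.7 and 729.6 ± 23.6 CPM with Lenti-Con and Lenti-Vsir, and CSF1, a macrophage growth factor gene, 334 ± 23.3 and 302 ± 29.2 CPM. On FPKM with limma the inflammatory cytokines list passed in 7 settings, over 9 members in place of 18, and its adjusted p ran from 0.011 to 0.37 over all other fits. Without Lenti-Con 1 its median was -0.00067.

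The chemokines list passed camera with lower values in Lenti-Vsir (adjusted p = 0.035), and had an adjusted p of 0.43 with an estimated correlation. Its median was -0.03, with 11 of 19 members below 0. The mean scores of the chemokines list were 0.0036 ± 0.14 and -0.0036 ± 0.078 with Lenti-Con and Lenti-Vsir (exact permutation p = 0.9). Its mean log2 difference was 0.037 in size, as large in 8 of 10 splits of the libraries and 0.156 at most, though only the real split called it. With GC and length trends removed the chemokines list had an adjusted p of 0.093. CCL3 passed edgeR adjusted over the list alone (adjusted p = 0.0037), an adjustment not made across lists. CCL5, another chemokine for T cells and monocytes, measured 236 ± 18.7 and 215 ± 16.5 CPM. The chemokines list was lost without Lenti-Con 1 (adjusted p = 0.097), Lenti-Con 3 (0.15), Lenti-Vsir 2 (0.095) or Lenti-Vsir 3 (0.096), in a range from 0.0097 to 0.17 over all other fits.

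Targets of NF-kB, the transcription factor of inflammatory signalling, also passed camera with lower values in Lenti-Vsir, with a median of -0.04 and 20 of 27 members below 0 (adjusted p = 0.013, and 0.43 with an estimated correlation). TNFAIP8, named after its values were seen, passed edgeR adjusted over the list alone (adjusted p = 0.045) and measured 76.0 ± 3.57 and 63.04 ± 3.86 CPM. This adjustment, too, was not made across lists. BTG2 measured 290.4 ± 12.8 and 270.5 ± 7.11 CPM and BCL2A1 98.9 ± 3.46 and 90.8 ± 1.39 CPM. The immediate early genes list had a median of -0.05, with 21 of 32 members below 0 (adjusted p = 0.013, and 0.43 with an estimated correlation), and DUSP6 measured 987 ± 20.3 and 958 ± 42.2 CPM and SPRY2 495 ± 8.99 and 506 ± 11.4 CPM. Without Lenti-Con 2 or Lenti-Vsir 1 the NF-kB target genes list had an adjusted p of 0.088 and 0.097, in a range from 0.0022 to 0.097 over all other fits. Without Lenti-Con 2, Lenti-Vsir 2 or Lenti-Vsir 3 the immediate early genes list had an adjusted p of 0.062, 0.067 and 0.096, in a range from 0.0028 to 0.15.

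The type I interferon response list had the smallest list p and lay lower in Lenti-Vsir, with a median of -0.16 and 37 of 38 members below 0 (camera adjusted p = 2.3e-11, and 0.52 with an estimated correlation). IFI6 measured 163 ± 23.6 and 141 ± 23.1 CPM with Lenti-Con and Lenti-Vsir, and the tetherin gene BST2 132 ± 12.1 and 117 ± 16.6 CPM. The mean score of the list was -0.09 in Lenti-Con 1, below the 0.04 of Lenti-Vsir 1, so the groups overlapped. The list was called in 7 of 10 splits of the libraries, with an adjusted p as small as 8.6e-31 and a mean log2 difference of up to 0.26 in size, against 0.17 in the real split. Without Lenti-Con 3 the median of the type I interferon response list was -0.06 (adjusted p = 0.010), and over all other fits its adjusted p ran from 3.4e-24 to 0.010. The interferon gamma response list did not pass (median -0.06, camera adjusted p = 0.10), and ICAM1 measured 314 ± 6.35 and 294 ± 4.52 CPM and FCGR1A 162 ± 7.82 and 160.3 ± 5.26 CPM.

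The NRF2 and oxidative stress list had a median of -0.06, with 20 of 24 members below 0 (camera adjusted p = 0.0064, and 0.43 with an estimated correlation). The ferritin genes FTL and FTH1, which store iron, measured 7906 ± 328 and 7426 ± 197 CPM and 5831 ± 97.6 and 5485 ± 329 CPM with Lenti-Con and Lenti-Vsir, and pseudogene copies make both counts uncertain. NRF2 was the 1 list that passed fry (adjusted p = 0.042).

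The lists of cell cycle genes lay higher in Lenti-Vsir, though not each named member did. The S phase and DNA replication list had a median of 0.09, with 25 of 30 members above 0 (camera adjusted p = 0.0012, and 0.43 with an estimated correlation). All 3 Lenti-Vsir scores exceeded the Lenti-Con scores (exact permutation p = 0.1, the smallest value this design allows). Scores of the groups did not overlap in 5 of 41 lists, where chance gives 10%. SLBP, the histone mRNA binding protein, measured 63.3 ± 0.292 and 59.96 ± 4.65 CPM with Lenti-Con and Lenti-Vsir. The mitosis list had a median of 0.08, with 23 of 30 members above 0 (camera adjusted p = 0.0064, and 0.67 with an estimated correlation), CCNB1 measured 43.0 ± 3.13 and 47.3 ± 3.17 CPM and CDC20 112 ± 13.5 and 112 ± 4.56 CPM, and the list was called in 9 of 10 splits of the libraries. Without Lenti-Con 3, whose mitosis score of -0.23 was the lowest, the mitosis list had an adjusted p of 0.93 and the direction of the test turned; without Lenti-Vsir 2 it was 0.093, in a range from 4.2e-05 to 0.93 over all other fits. The S phase and DNA replication list had an adjusted p of 0.059 without Lenti-Vsir 3, in a range from 0.00012 to 0.059.

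**Figure D2:**
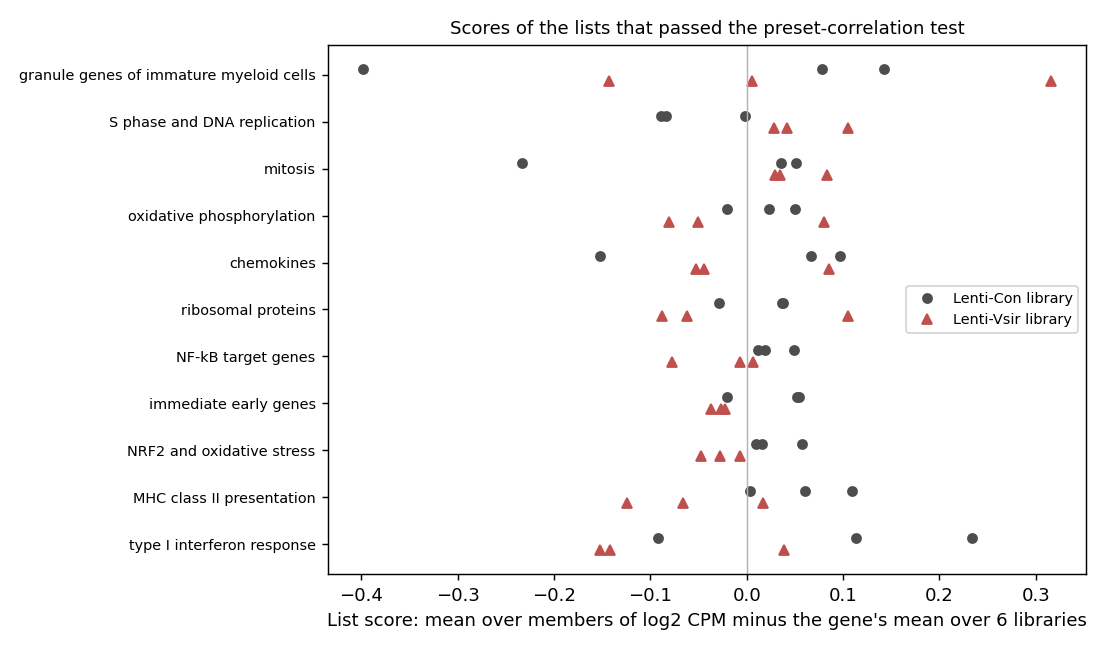
Score of each of the 11 lists that passed camera with a preset correlation (y axis), as the mean over members of log2 CPM centred on each gene's mean over the 6 libraries (x axis), for Lenti-Con (circles) and Lenti-Vsir (triangles) libraries. The scores of the groups did not overlap for the S phase, NRF2, NF-kB and immediate early lists. Type I interferon scores did overlap, with Lenti-Con 1 at -0.09 and Lenti-Vsir 1 at 0.04.

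Granule genes of immature myeloid cells had a median of 0.09, with 12 of 14 members above 0 (camera adjusted p = 0.035, and 0.61 with an estimated correlation), and AZU1 measured 541 ± 30.7 and 555 ± 77.6 CPM and CLEC11A 416 ± 36.1 and 433 ± 45.5 CPM with Lenti-Con and Lenti-Vsir. The ribosomal proteins list had a median of -0.03, with 42 of 52 members below 0 (adjusted p = 0.035, and 0.80 with an estimated correlation), and RPL8 measured 972 ± 37.8 and 946 ± 77.2 CPM and RPS12 300.3 ± 16.1 and 295 ± 28.6 CPM. The oxidative phosphorylation list had a median of -0.03, with 25 of 35 members below 0 (adjusted p = 0.041, and 0.73 with an estimated correlation), and ATP5F1B measured 525 ± 7.16 and 514 ± 26.9 CPM and CYC1 177 ± 4.85 and 172 ± 9.28 CPM. Of 10 splits of the libraries, 4 called the granule list, 8 the ribosomal proteins list and 5 the oxidative phosphorylation list, and the mean log2 difference was as large as in the real split in 5, 8 and 7. The granule genes of immature myeloid cells list was lost without Lenti-Con 2 (adjusted p = 0.19), Lenti-Con 3 (0.35) or Lenti-Vsir 1 (0.79), in a range from 0.00037 to 0.79 over all other fits. Without Lenti-Con 1, Lenti-Con 3, Lenti-Vsir 2 or Lenti-Vsir 3 the ribosomal proteins list had an adjusted p of 0.31, 0.25, 0.93 and 0.65 (from 1.0e-14 to 0.93 over all other fits), and the direction of the test turned without Lenti-Vsir 2. Without the same libraries the oxidative phosphorylation list had an adjusted p of 0.39, 0.15, 0.88 and 0.42 (from 4.4e-07 to 0.88 over all other fits).

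Over all lists, camera with the preset correlation called 11 of 41, 8 lower and 3 higher in Lenti-Vsir. With an estimated correlation it called 0, with 4 lists at an unadjusted p under 0.05, and fry called 1. The number called was 7 without Lenti-Con 2, 5 without Lenti-Con 3, and 6 without Lenti-Vsir 2 or Lenti-Vsir 3, of which 5 were among the 11 in either case. Without Lenti-Con 1 it was 12, with 8 of the 11. Over all genes edgeR called 0 list members, and adjusted over the list alone it called 2, CCL3 and TNFAIP8. That adjustment was made within each list and not across the 41 lists, so a few such calls would be expected by chance.

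**Figure D3:**
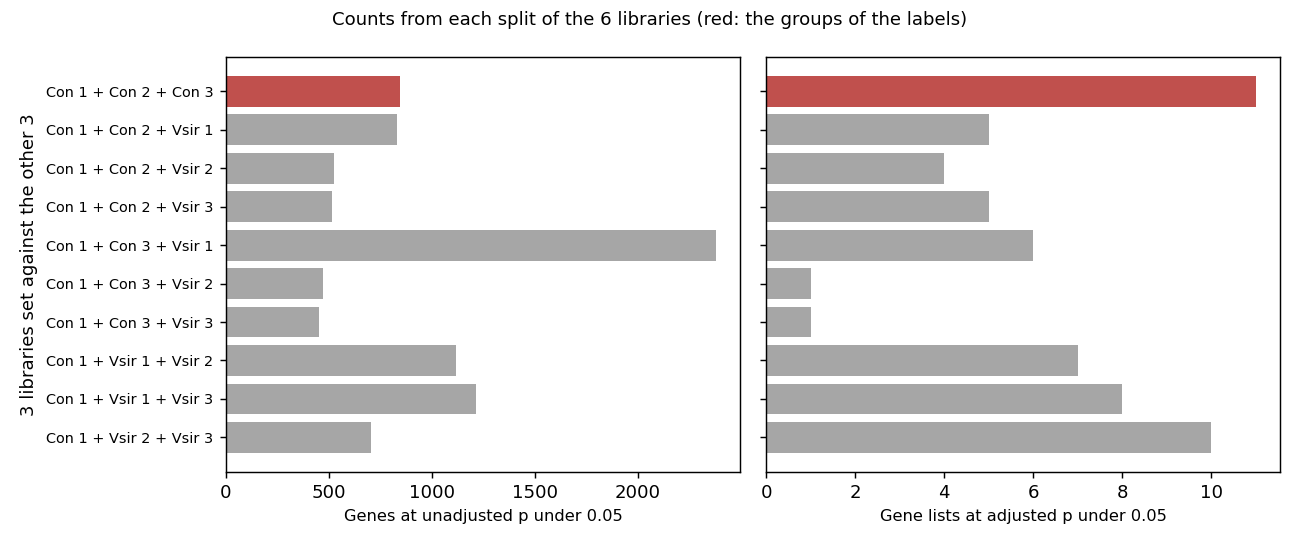
Genes at an unadjusted p under 0.05 (left x axis) and lists at an adjusted p under 0.05 by camera with the preset correlation (right x axis) for each split of the 6 libraries into 3 against 3 (y axis). The groups of the labels (red) gave 844 genes and 11 lists, and the split of Lenti-Con 1, Lenti-Con 3 and Lenti-Vsir 1 against the rest gave 2377 genes and 6 lists.

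Monocyte and macrophage markers did not pass, with a median of -0.0098 (camera adjusted p = 0.99), and CSF1R, the receptor of CSF1, measured 1298 ± 30.9 and 1316 ± 12.8 CPM with Lenti-Con and Lenti-Vsir. Medians were -0.01 for alternatively activated macrophage markers, -0.02 for costimulatory ligands, 0.01 for inhibitory immune receptors and ligands, -0.03 for partners of VISTA and close B7 genes, and -0.0078 for toll-like receptor and inflammasome genes, with camera adjusted p from 0.39 to 0.79. The immune checkpoint gene CD276 measured 556 ± 15.9 and 545 ± 13.3 CPM and NLRP3, an inflammasome sensor gene, 134 ± 2.45 and 131 ± 5.68 CPM.

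No list of markers of other cell types passed. The members with the highest FPKM were TRAC for T cells (49.8 ± 6.06 and 50.3 ± 2.76 CPM), FCRLA for B cells (4.63 ± 0.383 and 4.19 ± 0.513 CPM), TAGLN for fibroblasts (7.92 ± 1.33 and 8.96 ± 1.54 CPM), CLDN7 for epithelium (13.1 ± 0.6668 and 12.7 ± 1.16 CPM) and CRABP1 for packaging cells (4.94 ± 1.35 and 4.67 ± 1.65 CPM). List medians were 0.10 for T cell, -0.13 for B cell, -0.02 for fibroblast, -0.02 for epithelial and 0.05 for packaging cell markers, with camera adjusted p of 0.73, 0.26, 0.75, 0.79 and 0.54. Platelet and erythroid markers had fewer than 5 tested members and were not tested as a list, and GP1BA measured 0.723 ± 0.302 and 0.868 ± 0.374 CPM. Mitochondrially encoded transcripts, a sign of RNA quality, had a median of 0.04 with 13 of 13 members above 0 (camera adjusted p = 0.12).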

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

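Of the tests in this part, limma-voom, the minimum count of 50 and the removal of GC and length trends were chosen after seeing the data. VSIR kept a log2 difference above 0 in every fit, from 0.14 to 0.30, and passed in none. DESeq2 called 8 genes higher and 18 lower in Lenti-Vsir, and limma-voom 1 higher; the cause was not tested. Omission of 1 library gave 0 to 3 genes higher and 0 to 4 lower: 1 lower without Lenti-Con 3, 3 higher and 2 lower without Lenti-Vsir 2, and 4 lower without Lenti-Vsir 3. Same-numbered libraries of the 2 groups had correlations of deviations of 0.02, 0.03 and -0.03, and not every library correlated best with its own number. These correlations showed no pairing by number, but they do not exclude a shared batch. Lenti-Con 1 and Lenti-Vsir 1 had GC slopes of 0.042 and 0.065 log2 per 10% GC. Every other library had a slope from -0.042 to -0.016. With the replicate block, 1 gene was higher and 0 lower, and 12 lists were called. Each of the 10 genes named by the rule of smallest p (with a symbol, at least 2 FPKM and groups that did not overlap) kept its sign in the 21 to 23 alternatives where it was tested. The alternatives used the same libraries that picked these genes. With groups that did not overlap, a change of sign was hardly possible, so the kept signs lend these differences no support.

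The count of 11 lists fell to 0 with an estimated correlation and to 1 with fry, and ran from 5 to 12 on omission of 1 library; it was 7 without Lenti-Con 2, 5 without Lenti-Con 3, and 6 without Lenti-Vsir 2 or 3. In the other fits it was 10 to 16, but these were not always the same lists. Of the 11 reported, 6 were kept with quantile scaling of FPKM, 7 at a minimum of 5 FPKM, 8 with GC and length trends removed, 9 with no FPKM filter and 10 or 11 in the remaining fits. On omission of Lenti-Con 1, 2 or 3 there were 8, 7 and 5 kept, and of Lenti-Vsir 1, 2 or 3 there were 9, 5 and 5. The MHC class II list had an adjusted p of 0.43 with an estimated correlation and 0.22 with fry, and medians from -0.15 to -0.069 on omission of 1 library. The inflammatory cytokine list passed on FPKM with limma, with medians of -0.131 at pseudocount 1, with no trend and with robust variances, -0.135 at pseudocount 0.1, -0.083 at 5, -0.130 with median-of-ratios scaling and -0.091 with quantile scaling, where fewer members were tested; at a minimum of 5 FPKM it had too few members to test.

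For 2 called lists the direction of the test turned on omission of 1 library: medians ran from 0.015 to 0.136 for mitosis and from -0.092 to 0.0018 for ribosomal proteins. It also turned in 57 fits of 15 lists that passed neither in that fit nor in the reported one, all with a reported adjusted p of at least 0.10. The values that follow are medians, which need not change sign with the test. For TGF-beta response it turned with DESeq2 (0.014), with trends removed (0.025), with no low-count filter (0.013), and on FPKM at pseudocount 1, with no trend and with robust variances (0.0075), at pseudocount 0.1 (0.0082) and 5 (0.0054), with median-of-ratios scaling (0.0083), no filter (0.017) and a minimum of 5 (-0.0025). For hypoxia response it turned on FPKM at pseudocount 1, with no trend and with robust variances (0.021), at pseudocount 0.1 (0.022) and 5 (0.010), with median-of-ratios (0.0215) and quantile scaling (0.0105) and a minimum of 5 (0.039). With no low-count filter it turned for T cell markers (0.027), apoptosis regulators (0.017), epithelial markers (-0.0100) and monocyte markers (-0.016), and with a minimum count of 50 for T cell (0.033) and fibroblast markers (0.055). On FPKM it turned with no filter for epithelial (-4.2e-05) and monocyte markers (-0.0083), at a minimum of 5 for costimulatory ligands (-0.0092) and inhibitory receptors (-0.039), and with quantile scaling for VISTA partners (0.0051) and the unfolded protein response (0.0039). The cause was not tested.

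On omission of 1 library, medians ran from -0.030 to 0.139 for packaging cell markers, -0.0095 to 0.208 for T cell, -0.178 to 0.072 for epithelial and -0.022 to 0.076 for fibroblast markers. They ran from 0.0026 to 0.030 for TGF-beta response, -0.068 to 0.048 for alternatively activated macrophage markers, -0.017 to 0.085 for ATF4 targets, -0.0052 to 0.030 for apoptosis regulators and -0.019 to 0.0092 for hypoxia response. For monocyte markers the range was -0.0053 to 0.0031, for VISTA partners -0.035 to 0.018, and for toll-like receptor genes -0.034 to 0.0083. The chi-square per degree of freedom between replicates, a ratio of variances, was 13.2 to 26.0 over genes with at least 50 counts. The median chi-square of a gene was 6.27 to 11.7 times that of counting noise. In simulated data 17 of 50 genes changed 1.5-fold were recovered, all of them among the 19 with at least 10 CPM, so changes of that size at lower expression would be missed.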

Other observations

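The tests of the gene lists and annotation terms were fixed before the data were examined, and those of an exchanged library and of GC and length trends before their results were seen. The other tests of explanations in this part were chosen after the results were seen. Among lists of metabolism and stress, cholesterol synthesis genes had a median log2 difference of 0.05 with 19 of 24 members above 0 (camera adjusted p = 0.053), and SQLE, a rate-limiting enzyme of sterol synthesis, measured 655 ± 5.23 and 662 ± 17.1 CPM with Lenti-Con and Lenti-Vsir, while INSIG1 measured 284 ± 2.76 and 279.5 ± 8.75 CPM. LXR and fatty acid genes had a median of 0.06 (adjusted p = 0.095), with FABP4 at 461 ± 35.6 and 477 ± 32.0 CPM and FABP5 at 719.7 ± 40.8 and 694 ± 54.7 CPM, and replication-dependent histones 0.24 (adjusted p = 0.095), with H2BC21 at 12.8 ± 0.551 and 14.2 ± 1.05 CPM and H2BC12 at 21.2 ± 2.60 and 21.7 ± 1.07 CPM. Amino acid response and ATF4 targets had a median of 0.06 (adjusted p = 0.10), p53 targets -0.05 (0.14), MYC targets -0.02 (0.17), lysosome genes -0.03 (0.25) and glycolysis genes -0.03 (0.45), with the p53 targets CDKN1A at 701 ± 30.1 and 659.5 ± 27.4 CPM and GDF15 at 658 ± 56.6 and 639.6 ± 48.8 CPM. Heat shock, unfolded protein response, hypoxia and TGF-beta lists had medians of 0.0035, -0.01, -0.01 and 0.01, with adjusted p of 0.39, 0.60, 0.74 and 0.99.

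For 6 lists the median, the mean and the test differed in sign: complement and coagulation (median -0.03, mean 0.04, adjusted p = 0.26), cell adhesion and matrix genes (-0.03, 0.04, 0.26), alternatively activated macrophage markers (-0.01, 0.05, 0.61), VISTA partners (-0.03, 0.04, 0.79), apoptosis regulators (0.02, -0.0046, 0.98) and monocyte markers (-0.01, 0.0028, 0.99). Of 1823 annotation terms camera called 0 with the preset correlation, with 155 at an unadjusted p under 0.05, and 0 with an estimated one, with 36. The 3 terms with the smallest adjusted p (0.088) were graft-versus-host disease and rheumatoid arthritis, with medians of -0.13 and -0.05, and DNA replication initiation, with 0.09.

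The first pattern was the small difference in VSIR counts, with a ratio of 1.17. The lower 95% bound of 1.02 argues against silencing by at least 1.5-fold at the transcript level, and the upper bound of 1.35 against counted added transcripts of that size. No exchange of 1 library between the groups would hide a 1.5-fold difference in these counts, since the widest bound over the 9 single exchanges was 1.35. Whether such an exchange took place cannot be told from VSIR counts that lie this close together. Transcripts of a vector that human gene counts leave out would also leave the ratio near 1.17, and this stays open because no vector sequence was counted.

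The second pattern was the 11 lists called with the preset correlation. With 10 splits of the 6 libraries a share under 0.05 cannot be reached: the real split called 11 lists, 1 of 10 splits gave as many, and the highest other called 10. After GC and length trends were removed, the real split was no longer the highest. It then called 10 lists, and the split of Lenti-Con 1, Lenti-Vsir 2 and Lenti-Vsir 3 against the rest called 12. Removal of GC and length trends kept 8 of the 11 calls, a value between those that would have argued for or against these trends; it ended those of the chemokines list (median -0.03 before and -0.0060 after, adjusted p = 0.093), the ribosomal proteins list (-0.03 and -0.02, 0.079) and the oxidative phosphorylation list (-0.03 and -0.02, 0.090), whose medians moved toward 0. With an estimated correlation 0 lists passed, but a simulated shifted list was not recovered by it either, so that loss alone decides nothing. The estimate was 0.83 for ribosomal proteins, 0.54 for type I interferon, 0.50 for oxidative phosphorylation, 0.45 for mitosis and 0.20 for granule genes. For those lists the preset value of 0.01 was too low and its p-values were too small. The estimates of 0.076 for S phase and 0.031 for MHC class II were also above the preset value. By these estimates the p-values of both lists were too small as well. The estimate for NF-kB targets, 0.011, was close to the preset value. Chemokines (-0.026), immediate early genes (-0.0045) and NRF2 (-0.031) had no estimate above the preset value. The split of Lenti-Con 1, Lenti-Con 3 and Lenti-Vsir 1 against the rest gave 2377 genes at an unadjusted p under 0.05 against 844 in the real split, and 1718 after the trends were removed; it called 0 genes by adjusted p, and its cause stays open.

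The real split called 0 genes, as many or more were called in 10 of 10 splits, and the highest other called 5; the real split called 0 annotation terms, as many or more were called in 10 of 10, and the highest other called 81. A count of 0 is matched by every split, so these counts decide nothing.

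The third pattern was 121 genes at 0 counts in a library and at least 50 in another. Of these, 80.2% overlapped another gene on the same strand, against 19.8% to 35.6% in 95% of 10000 random lists matched on mean expression, so reads assigned to 1 or another of overlapping genes are a candidate explanation. GET1-SH3BGR had 0 counts in each Lenti-Con library and 38, 106 and 139 with Lenti-Vsir, ENSG00000290609 had 0 against 54, 52 and 46, and ENSG00000285565 had 84, 26 and 45 against 0; they were chosen after their values were seen, edgeR called 0 of them (adjusted p of 0.15, 0.15 and 0.33) and DESeq2 all 3. In all, 22 of the 121, or 18.2%, had groups that did not overlap, where chance gives 10% and the highest other split gave 12.4%. An effect of the vector on these genes stays open, since overlapping genes are not independent and 10 splits are too few.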
